A study of Mus musculus with 16 samples.

How the data were processed

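RNA was measured in 16 mouse libraries, 2 for each of 8 groups, made by the Smart-seq2 protocol from single colonies. Induced pluripotent stem cells (iPSC), which carry GFP, and trophectoderm stem cells (TSC), which carry RFP, were either cultured alone or mixed so that they assembled into structures with a green iPSC part and a red TSC part. All cultures grew on 5% Matrigel in a medium with FGF4 at 12.5 ng/ml and heparin at 500 ng/ml. For the last 24 hours before collection on day 3 they were kept with or without BMP4, at a dose not given in the sources used here. The parts of an assembled structure were chosen under a fluorescence microscope, separated by hand and made into separate libraries. The 8 groups are therefore iPSC alone, TSC alone, the assembled iPSC part and the assembled TSC part, each without and with BMP4.

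The values used are the deposited FPKM (fragments scaled by transcript length and by the mapped total), a single table with 31663 gene symbols and 1 column per library. Per the submitters' processing notes, CASAVA and TopHat2 were used and the genome builds mm9 and hg19 occur, with no roles or versions. The program that computed FPKM, its annotation and any filter are not given in the sources used here, so reads shared between paralogs or overlapping genes on opposite strands may be split in ways that cannot be checked. Read counts and depth are unknown, so values carry no counting interval and a value of 0 has no known upper limit. Every column of the table was used, and 12 entries share a symbol with another entry and were kept apart.

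Genes with at least 1 FPKM in at least 2 libraries were tested, which left 13406. Values were taken as log2(FPKM + 1) without further scaling and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend) as 8 group means over all 16 libraries, with 8 residual degrees of freedom. There were 13 comparisons: 10 between pairs of groups, 2 interactions that ask whether the effect of BMP4 differs between assembled cells and cells cultured alone, and the mean of the 4 BMP4 effects. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. No label says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Replicate numbers showed no clear pairing in the values, and no label says whether libraries with the same number share a structure or preparation.

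In each comparison, 28 gene lists were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of that comparison, and again with a correlation estimated from the data. Members were counted past the threshold over all genes tested and adjusted over the list alone. Of 364 list tests, 103 passed at the preset correlation and 0 passed with an estimated correlation, where limma camera gave 30 with an unadjusted p under 0.05 and a lowest adjusted p of 0.0632. The comparisons, the lists and the rule for naming genes were fixed before the data were examined. The rule took up to 10 genes per direction with the largest log2 change among those past the threshold, with no overlap between libraries and a mean of at least 5 FPKM in the higher group, leaving out predicted, microRNA, snoRNA and pseudogene names. It added up to 4 members past the threshold per list, 27 genes named whatever their result and, where fewer than 10 genes passed, up to 10 with the smallest p. A named gene outside it is marked as chosen after its values were seen.

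Alternatives were a pseudocount of 0.1, no filter, quantile normalization, upper quartile rescaling, library quality weights, a block for the replicate number, a fit of only the groups compared, a threshold of 2-fold and leaving out each library. Chosen after seeing the data were a fit with predicted names left out and totals rescaled, and a fit without replicate 2 of the assembled iPSC part with BMP4 and replicate 2 of the assembled TSC part. GC content and transcript length came from the GENCODE annotation by symbol, for 13380 of the tested genes (99.8%). The fit was tested on simulated data with the design of the BMP4 comparison in iPSC alone, where it recovered 14 of 67 genes changed 2-fold, 53 of 67 changed 4-fold and 62 of 66 changed 8-fold, with 6 of 135 calls wrong. For the interaction in TSC it recovered 2 of 67, 37 of 67 and 50 of 66, with 4 of 93 calls wrong. The simulated noise was independent between libraries, with the same spread of a gene in all groups. Only genes at a mean level of at least 5 FPKM, on the log2 scale, were changed. In the data, replicates differed more than 2-fold in 2083 genes in TSC alone and 454 in iPSC alone. These shares therefore do not carry over to the real comparisons. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.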

Results

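Cell type separated the libraries most. On the first principal component, with 38.9% of the variance, the 8 libraries of iPSC origin lay between -58.0 and -26.3 and the 8 of TSC origin between 33.8 and 73.9. On the second, with 16.3%, all 8 libraries of assembled cells had positive scores (13.2 to 41.5), as had replicate 1 of TSC alone with BMP4 (18.5), and the other 7 libraries of cells cultured alone had negative scores (-59.3 to -15.2). Replicates correlated across genes with Pearson's r from 0.929, in the assembled iPSC part with BMP4, to 0.973, in iPSC alone. Changes are given as differences of log2(FPKM + 1) ± SE from limma, a scale that understates the fold of genes with low levels, and levels as mean FPKM ± SD with n = 2 libraries per group.

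**Figure D1:**
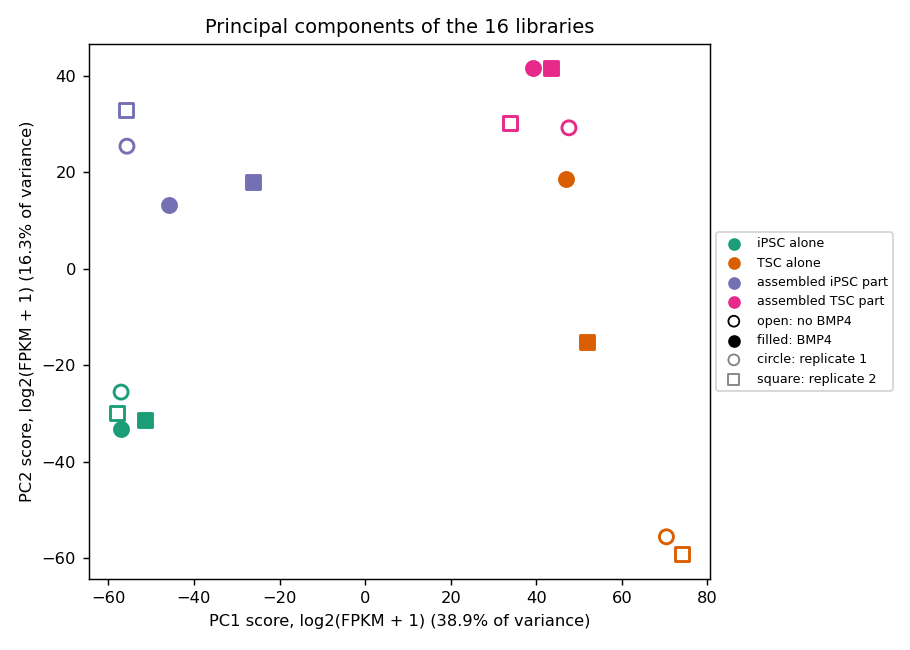
Scores of the 16 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis. The components hold 38.9% and 16.3%, and the second is positive for all 8 assembled libraries and for replicate 1 of TSC alone with BMP4.

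Without BMP4, colonies of TSC and iPSC cultured alone differed in many, but not all, of the genes that mark each cell type. Plac1, which the placenta needs for normal growth, stood at 519 ± 319 FPKM in TSC and 0.353 ± 0.0608 in iPSC (8.44 ± 0.78, limma adjusted p = 1.49e-05, n = 2 per group). Igf2, an imprinted growth factor, stood at 1225 ± 170.4 against 1.87 ± 0.772 (8.76 ± 1.07). The trophoblast regulators Gata3 (5.11 ± 0.48), Tfap2c (5.27 ± 0.39) and Dlx3 (5.64 ± 0.30) rose as well, as did the keratin Krt18 (4.98 ± 0.44). Pou5f1, the central factor of pluripotency, stood at 0.533 ± 0.707 FPKM in TSC against 273 ± 76.1 in iPSC (-7.53 ± 0.65, limma adjusted p = 1.03e-05). Nanog fell by 4.15, and Fgf5, a marker of the postimplantation epiblast, fell by 5.46.

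Of 31 measured genes of trophoblast stem cells and extraembryonic ectoderm, 18 were higher in TSC alone and 3 lower (20 and 3 adjusted over the list alone), with a median change of 2.40 (limma camera adjusted p = 4.74e-06; adjusted p = 0.419 with an estimated correlation). Of 16 genes of differentiated trophoblast, 11 were higher and 2 lower (12 and 2 adjusted over the list alone), among them Ascl2 (4.95 ± 0.67) and the imprinted Phlda2 (6.72 ± 0.78) on the higher side (median 4.04, limma camera adjusted p = 7.78e-06; adjusted p = 0.215 with an estimated correlation). Of these 31 stem cell genes, 3 were thus lower and 10 did not pass. Eomes stood at 0.152 ± 0.0952 FPKM, below the 2.22 ± 0.272 of iPSC (-1.48 ± 0.35, limma adjusted p = 0.00575). Elf5 stood at 8.54 ± 4.28 against 0.313 ± 0.141 (2.79 ± 1.12, limma adjusted p = 0.0680). Elf5 passed with a pseudocount of 0.1 (4.34, limma adjusted p = 0.0474), as it did after rescaling without predicted names and in a fit of only these 4 libraries. Cdx2, named whatever its result, was at 1.94 ± 2.75 FPKM in TSC and 0.261 ± 0.0229 in iPSC (0.81 ± 0.62, limma adjusted p = 0.327). Esrrb, named in the same way, was at 0.0700 ± 0.0991 and 0.325 ± 0.0402 (-0.31 ± 0.68, limma adjusted p = 0.756). Neither passed. Of 18 formative and primed epiblast genes, 13 were lower and 0 higher over all genes and adjusted over the list alone, with 0 higher at an unadjusted limma p under 0.05 (median -2.36, limma camera adjusted p = 7.78e-06; adjusted p = 0.215 with an estimated correlation). Of 18 targets of FGF-ERK signalling, 12 were lower and 2 higher (13 and 3 adjusted over the list alone). Among them, Dusp6, a feedback phosphatase of ERK, stood at 0.125 ± 0.115 against 59.9 ± 3.63 and the factor Etv5 at 0.136 ± 0.102 against 45.9 ± 4.06 (median -2.08, limma camera adjusted p = 0.000131; adjusted p = 0.349 with an estimated correlation). Of 11 Nodal targets and ligands, 8 were lower and 2 higher, the same counts adjusted over the list alone. Nodal itself fell by 5.44 and its co-receptor Tdgf1 by 6.81 (median -3.39, limma camera adjusted p = 0.00811; adjusted p = 0.492 with an estimated correlation). In all, 4878 of 13406 genes passed, 2172 higher and 2706 lower in TSC. Without replicate 2 of iPSC alone, 3087 passed. Rescaling without predicted names moved the median of all genes from -0.11 to 0.00052. Changes of genes near 0 in TSC were larger in size with a pseudocount of 0.1, at -8.33 for Fgf5 and -3.25 for Eomes. The medians were then -4.998 for the epiblast genes and -4.58 for the FGF-ERK targets.

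**Figure D2:**
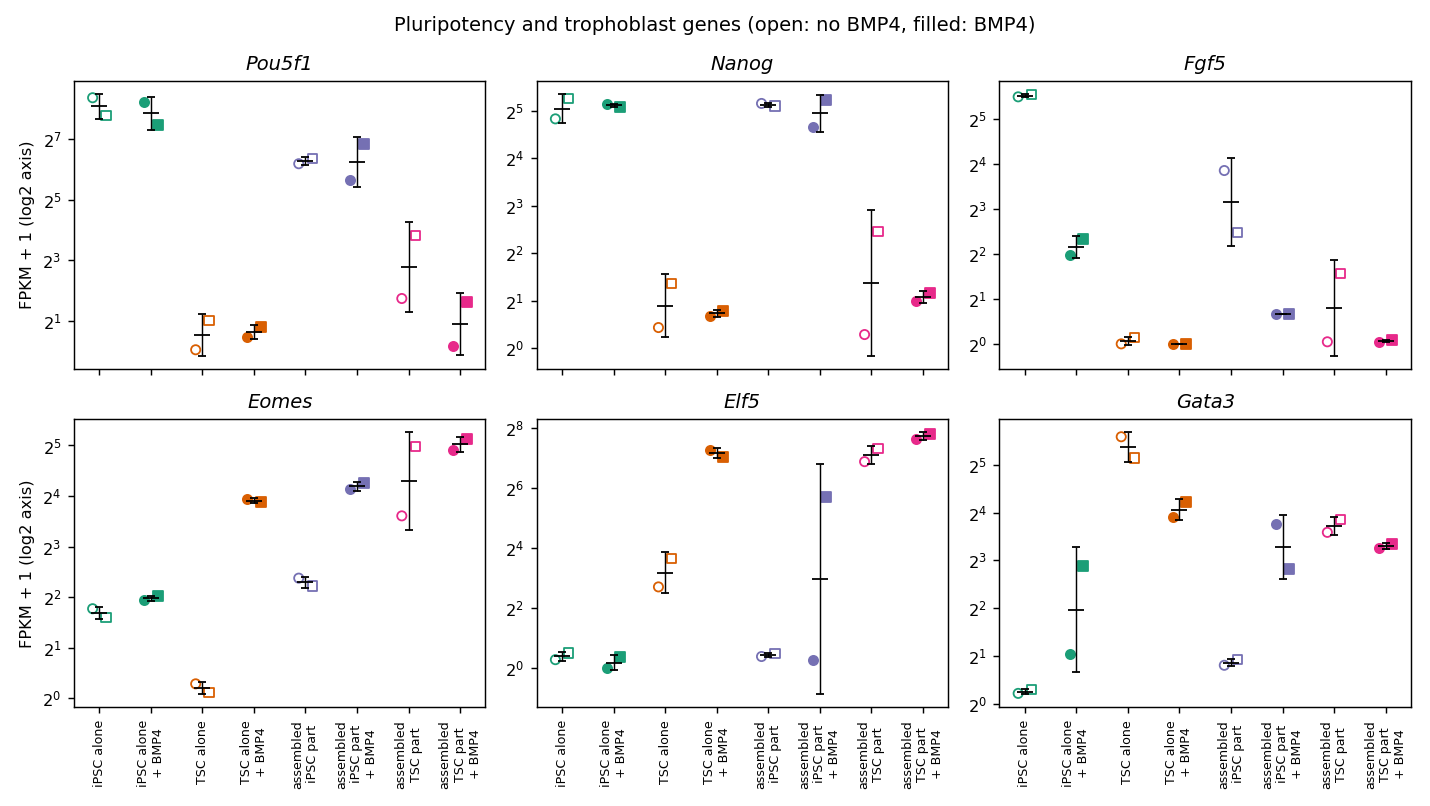
FPKM + 1 on a log2 axis of Pou5f1, Nanog, Fgf5, Eomes, Elf5 and Gata3 in the 16 libraries by group; circles are replicate 1, squares replicate 2, open symbols without BMP4, filled symbols with BMP4, and bars the mean ± SD of log2(FPKM + 1). Eomes stood at 0.152 FPKM in TSC alone and at 20.8 in the assembled TSC part.

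The assembled parts differed by lineage as well. In the TSC part without BMP4, Hand1, a regulator of trophoblast and mesoderm, stood at 389 ± 68.9 FPKM against 0.777 ± 0.244 in the iPSC part (7.77 ± 0.91, limma adjusted p = 0.000503, n = 2 per group). The trophoblast stem cell factor Elf5 stood at 137 ± 29.9 against 0.349 ± 0.0624 (6.67 ± 1.12, limma adjusted p = 0.00213), and the placental homeobox gene Esx1 at 127 ± 25.1 against 0.412 ± 0.0284. Id2, a target of BMP signalling, stood at 1255 ± 247 against 156 ± 34.4 (3.00 ± 0.42, limma adjusted p = 0.000845). In the iPSC part, T, the primitive streak factor, stood at 247 ± 14.5 FPKM against 8.64 ± 11.5 in the TSC part (-5.57 ± 0.84, limma adjusted p = 0.00131). Fgf8 (-4.86 ± 0.87), the Wnt target Sp5 (-4.20 ± 0.50), Nodal (-3.82 ± 0.57), Nanog (-3.75 ± 0.53) and Pou5f1 (-3.49 ± 0.65) were also lower in the TSC part.

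Of the 31 trophoblast stem cell genes, 23 were higher in the TSC part and 1 lower (26 and 1 adjusted over the list alone; median 3.03, limma camera adjusted p = 6.6e-12; adjusted p = 0.275 with an estimated correlation). Of 28 primitive streak and early mesoderm genes, 10 were lower and 5 higher (12 and 5 adjusted over the list alone), with T, Fgf8 and the activin antagonist Fst (-4.36 ± 0.67) lower and Hand1 and Gata4 (1.72 ± 0.29) higher (median -0.94, limma camera adjusted p = 0.00213; adjusted p = 0.414 with an estimated correlation). Of 15 Wnt targets, 6 were lower over all genes and adjusted over the list alone, and 0 higher, also at an unadjusted limma p under 0.05 (median -0.58, limma camera adjusted p = 0.000121; adjusted p = 0.275 with an estimated correlation). Of the 11 Nodal genes, 6 were lower and 1 higher (7 and 1 adjusted over the list alone; median -2.24, limma camera adjusted p = 0.000121; adjusted p = 0.275 with an estimated correlation). In all, 2271 genes passed, 1482 higher and 789 lower in the TSC part. The count was 1044 and 988 without replicates 1 and 2 of the iPSC part and 902 and 1473 without replicates 1 and 2 of the TSC part. Quantile normalization gave 1273 higher and 1180 lower with the median of all genes at -0.01, and upper quartile rescaling 1100 and 1290 with a median of -0.06, against 0.12 as deposited. With a pseudocount of 0.1, the changes were 3.12 for Gata4, -2.84 for the median of the streak genes and -1.05 for that of the Wnt targets.

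Genes of the other lineage were not equally low in all assembled libraries. In replicate 2 of the TSC part without BMP4, 60 genes chosen as iPSC-specific from the cells cultured alone stood at a median of 14.2% of their level in the assembled iPSC part, against 0.648% in replicate 1. Pou5f1 was at 13.17 FPKM in replicate 2 and 2.333 in replicate 1, Nanog at 4.505 and 0.2236, and T at 16.75 and 0.5391. In replicate 2 of the iPSC part with BMP4, 33 trophoblast genes stood at 42.4% of their level in the assembled TSC part, against 7.49% in replicate 1, while the iPSC genes stood at 79.8% and 80.3%. Elf5 was at 50.43 FPKM in that replicate 2 and 0.1931 in its replicate 1. The 60 and 33 genes were chosen after the values were seen. The 33 were chosen against untreated iPSC only, so genes that BMP4 raises in iPSC could enter. They include the paralogs Rhox4a to Rhox4g, whose reads cannot be placed with certainty. Among the 60, Eif2s3y, a gene of the Y chromosome, was at 16.1 and 0.055 FPKM in replicates 1 and 2 of the untreated assembled iPSC part. In the treated part it was at 48.22 and 5.754. Why its level differed was not tested.

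**Figure D3:**
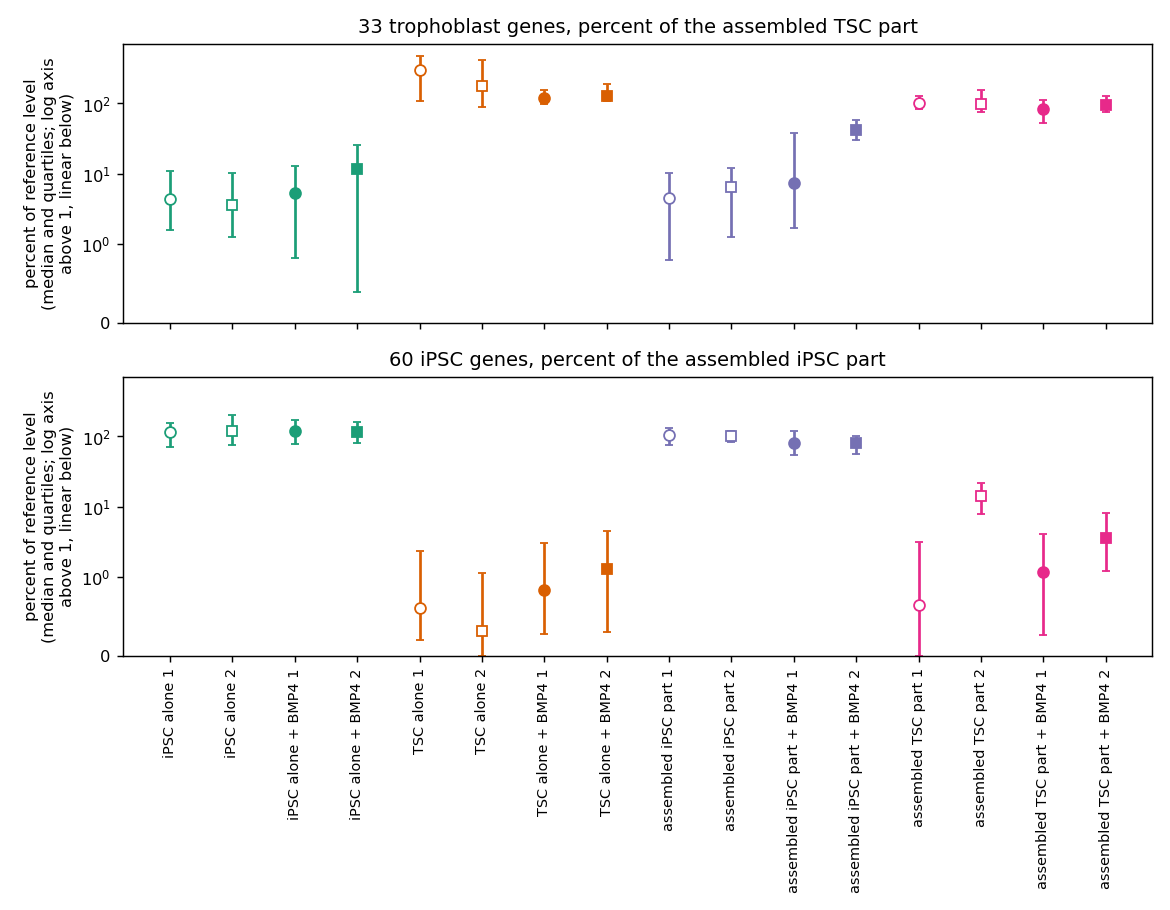
Level of trophoblast genes (33) and iPSC genes (60) in each library as a percent of their mean level in the assembled part of the matching cell type, on a symmetric log axis. That mean takes the libraries with and without BMP4 together. Points are medians over genes and lines the quartiles. Replicate 2 of the assembled iPSC part with BMP4 holds the trophoblast genes at 42.4%, and replicate 2 of the assembled TSC part the iPSC genes at 14.2%.

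Set against iPSC cultured alone, the assembled iPSC part held less RNA of the glycolytic enzymes Pfkl and Pkm and of Fgf5, and more of Evx1. Pfkl, a phosphofructokinase subunit, stood at 26.5 ± 5.83 FPKM against 207 ± 12.1 (-2.93 ± 0.44, limma adjusted p = 0.00485, n = 2 per group), and the pyruvate kinase Pkm at 628 ± 119 against 2335 ± 95.5 (-1.90 ± 0.31, limma adjusted p = 0.00530). The streak factor Evx1 stood at 4.52 ± 1.07 against 0.494 ± 0.0110 (1.87 ± 0.36, limma adjusted p = 0.00853). Fgf5 stood at 9.04 ± 6.35 against 45.1 ± 1.13 (-2.36 ± 0.47, limma adjusted p = 0.00999). T was at 247 ± 14.5 against 42.1 ± 3.53 FPKM (2.52 ± 0.84, limma adjusted p = 0.0696) and Pou5f1 at 76.2 ± 6.67 against 273 ± 76.1 (-1.80 ± 0.65, limma adjusted p = 0.0887), and neither passed. Nanog differed by 0.08 ± 0.53.

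Each of these calls rests on single libraries. Without replicate 2 of the assembled iPSC part, the limma adjusted p was 0.0632 for Pfkl, 0.0726 for Pkm, 0.0997 for Evx1 and 0.126 for Fgf5. Without replicates 1 and 2 of iPSC alone it was 0.0617 and 0.0679 for Evx1 and 0.0671 and 0.0791 for Fgf5. Sco2, an assembly factor of cytochrome c oxidase, was at 26.1 and 39.09 FPKM in the assembled iPSC part and at 2.48e-06 and 6.43e-07 in iPSC alone, values near 0 that may be failed estimates (limma adjusted p = 0.00253). It is the only 1 of 61 changed genes named by the rule that kept its call without any 1 of the 4 libraries. Of the 61, 48 and 50 lost the call without replicates 1 and 2 of iPSC alone, and 26 and 60 without replicates 1 and 2 of the assembled part.

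Of the 28 primitive streak genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.19, limma camera adjusted p = 0.00721; adjusted p = 0.706 with an estimated correlation). The median was 0.0960 without replicate 2 of iPSC alone, 0.40 after quantile normalization and 0.36 with a pseudocount of 0.1. Of the 15 Wnt targets, 2 rose and 0 fell (5 and 0 adjusted over the list alone, and 0 lower at an unadjusted limma p under 0.05; median 0.46, limma camera adjusted p = 0.00721; adjusted p = 0.706 with an estimated correlation). Their median was 0.30 without replicate 2 of the assembled part, 0.74 after quantile normalization and 0.70 with a pseudocount of 0.1. Of 24 genes of hypoxia and glycolysis, 6 fell and 0 rose (8 and 2 adjusted over the list alone; median -0.73, limma camera adjusted p = 0.0976), a list that did not pass. In all, 1585 genes passed, 279 higher and 1306 lower. Without replicates 1 and 2 of iPSC alone, 158 and 110 passed, and without replicates 1 and 2 of the assembled part, 739 and 6. Library quality weights gave 3985. The split followed the scaling. Quantile normalization gave 577 higher and 780 lower and upper quartile rescaling 774 and 713, while the median of all genes, -0.19 as deposited, was 0.00073 and 0.02, and -0.41 after rescaling without predicted names.

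**Figure D4:**
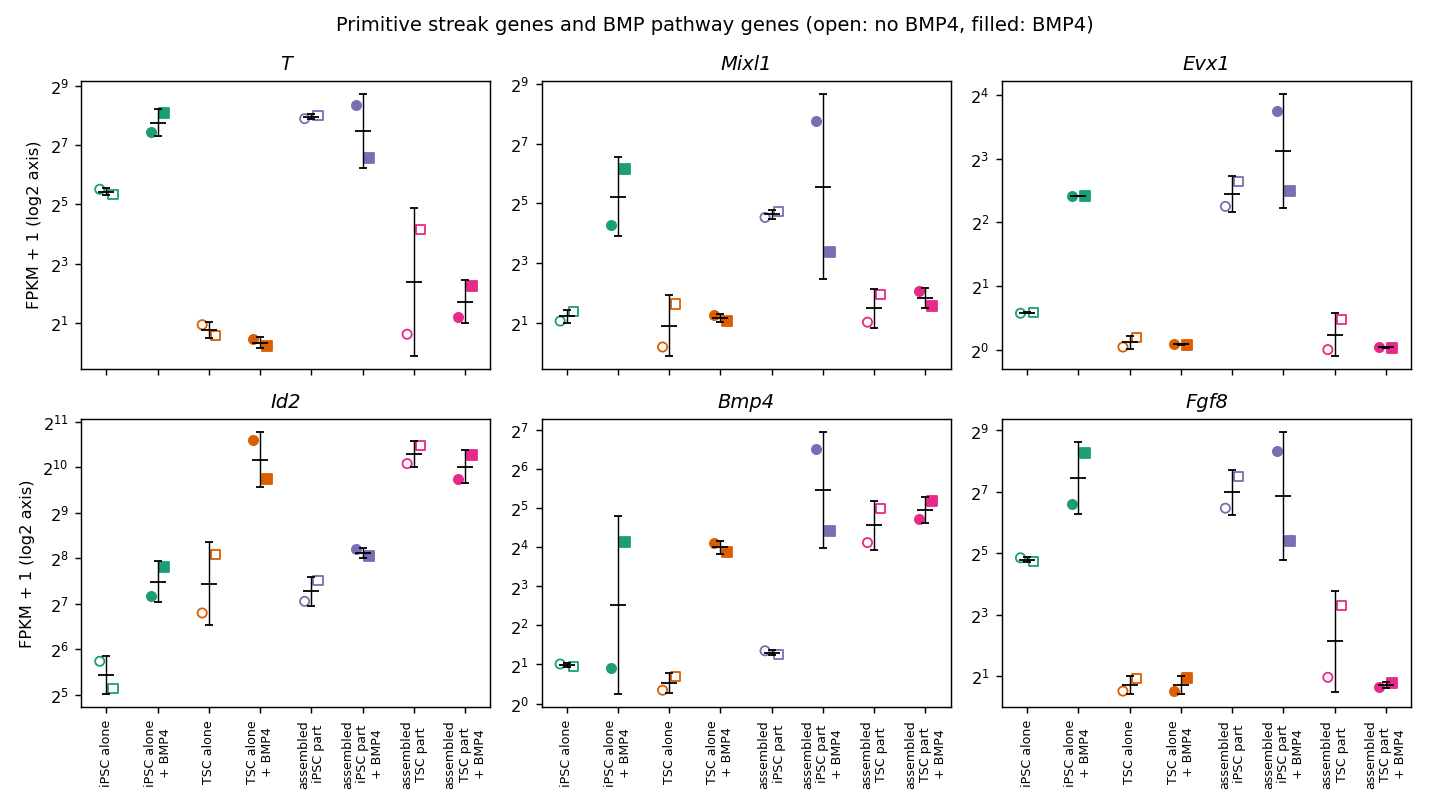
FPKM + 1 on a log2 axis of T, Mixl1, Evx1, Id2, Bmp4 and Fgf8 in the 16 libraries by group, with symbols and bars as in the plot of lineage markers: circles replicate 1, squares replicate 2, filled with BMP4, bars mean ± SD of log2(FPKM + 1). T stood at 42.1 FPKM in iPSC alone and 247 in the assembled iPSC part.

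The assembled TSC part differed from TSC alone in 2575 genes. Replicates of TSC alone differed more than 2-fold in 2083 genes, and a difference of these libraries cannot be told from an effect of assembly. Eomes stood at 20.8 ± 13.6 FPKM against 0.152 ± 0.0952 (4.09 ± 0.35, limma adjusted p = 6.44e-05, n = 2 per group) and the orphan receptor Esrrb at 13.4 ± 5.87 against 0.0700 ± 0.0991 (3.69 ± 0.68, limma adjusted p = 0.00341). Bmp4 stood at 23.7 ± 10.3 against 0.445 ± 0.252 (4.04 ± 0.82, limma adjusted p = 0.00573) and Id2 at 1255 ± 247 against 190.1 ± 113 (2.84 ± 0.42). Plac1 fell from 519 ± 319 to 2.75 ± 2.98 FPKM (-7.24 ± 0.78, limma adjusted p = 0.000212), and Pparg, a nuclear receptor needed in the placenta, from 75.7 ± 37.1 to 0.170 ± 0.0376 (-5.95 ± 0.59). The cell cycle inhibitor Cdkn1c (-5.65 ± 0.69), Gata2 (-3.38 ± 0.67) and Dlx3 (-2.84 ± 0.30) fell as well. Elf5 was at 137 ± 29.9 against 8.54 ± 4.28 FPKM (3.92 ± 1.12, limma adjusted p = 0.0283), a call lost without replicates 1 and 2 of TSC alone (limma adjusted p = 0.122 and 0.0596) and without replicates 1 and 2 of the assembled part (0.0992 and 0.121).

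Of the 18 FGF-ERK targets, 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.44, limma camera adjusted p = 8.57e-07; adjusted p = 0.336 with an estimated correlation). Etv4 rose by 4.27 ± 0.37, Etv5 by 3.05 ± 0.37, the feedback inhibitor Spry2 by 2.73 ± 0.38 and Dusp6 by 2.64 ± 0.43. Of the 16 genes of differentiated trophoblast, 9 fell and 0 rose (11 and 0 adjusted over the list alone, and 0 higher at an unadjusted limma p under 0.05; median -1.47, limma camera adjusted p = 3.66e-05; adjusted p = 0.336 with an estimated correlation). The 31 trophoblast stem cell genes went both ways, with 8 higher and 6 lower (10 and 10 adjusted over the list alone; median 0.83, limma camera adjusted p = 0.392). Of 22 epithelial junction and keratin genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone, and 0 higher at an unadjusted limma p under 0.05; median -0.95, limma camera adjusted p = 0.00113; adjusted p = 0.683 with an estimated correlation). Of 32 ribosomal protein genes, 26 rose and 0 fell (30 and 0 adjusted over the list alone, and 0 lower at an unadjusted limma p under 0.05), Rpl37 by 1.72 ± 0.26 (median 0.98, 0.51 after quantile normalization; limma camera adjusted p = 5.91e-14; adjusted p = 0.636 with an estimated correlation). Changes in this comparison followed transcript length (Spearman -0.223), and these transcripts are short. After a correction for GC content and length, chosen after the values were seen, 23 of the 32 passed, all higher, with a median of 0.83. Of the 2575 genes, 1208 were higher and 1367 lower. Without replicates 1 and 2 of the assembled part the count was 1038 and 1324, and it was 1398 without the pair of libraries that held genes of the other lineage, here replicate 2 of the assembled part with iPSC genes at 14.2%. It was 1510 with library quality weights and 3 in a fit of only these 4 libraries, where each gene named here missed the threshold. Rescaling without predicted names gave 742 higher and 2116 lower and moved the median of all genes from 0.03 to -0.24. Low levels in TSC alone gave larger changes with a pseudocount of 0.1, such as 6.26 for Eomes, 6.37 for Esrrb, 6.72 for Etv4, 5.24 for Etv5 and 4.85 for Dusp6, and a median of 2.90 for the FGF-ERK targets.

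**Figure D5:**
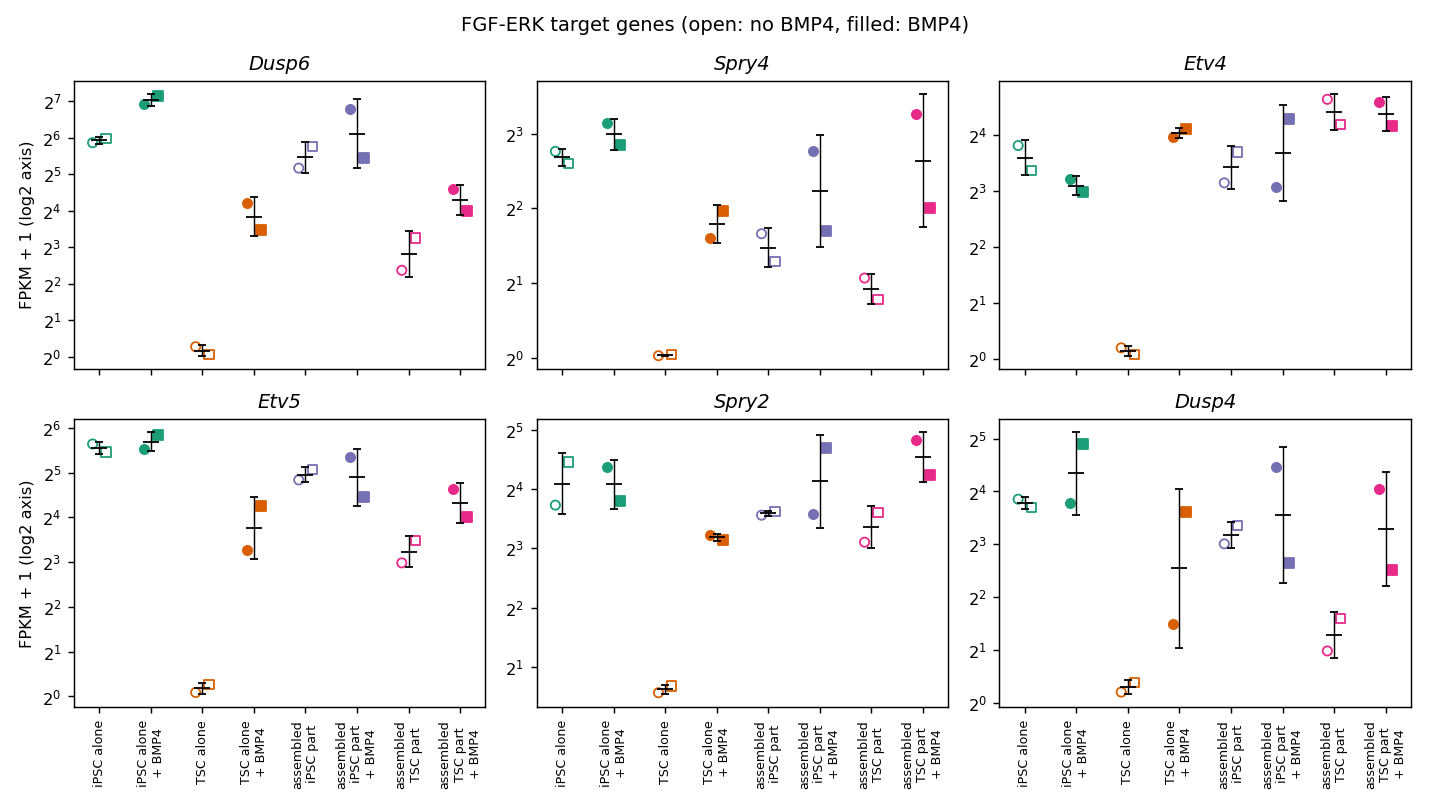
FPKM + 1 on a log2 axis of the FGF-ERK targets Dusp6, Spry4, Etv4, Etv5, Spry2 and Dusp4 in the 16 libraries by group, with circles for replicate 1, squares for replicate 2, filled symbols for BMP4 and bars for the mean ± SD of log2(FPKM + 1). Dusp6 stood at 0.125 FPKM in TSC alone, 13.8 in TSC alone with BMP4 and 6.33 in the assembled TSC part.

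In iPSC cultured alone, single genes rarely passed after 24 hours of BMP4. Id1, a direct target of BMP signalling, was at 317 ± 20.5 FPKM against 55.0 ± 14.4 (2.53 ± 0.88, limma adjusted p = 0.556, n = 2 per group) and Id2 at 183 ± 57.7 against 43.3 ± 12.8 (2.05 ± 0.42, limma adjusted p = 0.136). T was at 221 ± 69.7 against 42.1 ± 3.53 FPKM (2.33 ± 0.84, limma adjusted p = 0.588), and Mixl1, a factor of the primitive streak, at 18.61 and 70.31 against 1.34 ± 0.352. Fgf5 stood at 3.47 ± 0.761 against 45.1 ± 1.13 (-3.38 ± 0.47, limma adjusted p = 0.0181). Pou5f1 (-0.22 ± 0.65) and Nanog (0.07 ± 0.53) did not pass. The splicing factor Srsf2 stood at 59.8 ± 7.71 against 2.81 ± 0.523 (3.996 ± 0.41, limma adjusted p = 0.00118).

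Of 18 BMP targets, 0 passed over all genes, 10 were higher and 0 lower adjusted over the list alone, and limma gave the same 10 and 0 at an unadjusted p under 0.05 (median 0.95, limma camera adjusted p = 8.42e-12; adjusted p = 0.102 with an estimated correlation). Of 13 genes of extraembryonic mesoderm and amnion, 0 passed over all genes, while 6 were higher and 0 lower adjusted over the list alone and 7 and 0 at an unadjusted limma p under 0.05 (median 1.54, limma camera adjusted p = 1.13e-08; adjusted p = 0.0632 with an estimated correlation). Of the 28 primitive streak genes, 0 passed over all genes, with 3 higher and 0 lower adjusted over the list alone and 9 and 1 at an unadjusted limma p under 0.05 (median 0.91, limma camera adjusted p = 5.03e-06; adjusted p = 0.234 with an estimated correlation). Of the 18 epiblast genes, Fgf5 fell and 0 rose, with 3 lower and 1 higher adjusted over the list alone (median -0.69, limma camera adjusted p = 1.01e-06; adjusted p = 0.102 with an estimated correlation). The medians were 2.43 and 0.93 for extraembryonic mesoderm without replicates 1 and 2 of the treated cells, and 0.45 for the streak genes without that replicate 2. With a pseudocount of 0.1 they were 1.56 for the BMP targets and 1.43 for the streak genes.

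The 8 genes that passed in iPSC alone (3 higher, 5 lower, with 842 at an unadjusted limma p under 0.05) were Srsf2, Gm14870 and Evx1os on the higher side and Fgf5, Spon1, Pcsk2, Nrcam and Snord118 on the lower. Gm14870 and Snord118 were named only by the part of the rule that takes the smallest p. Gm14870 was at 35.55 and 67.68 FPKM in the treated libraries and at 0 in the other 14, and Snord118 at 203.7 and 66.62 in untreated iPSC alone and 0 elsewhere. Evx1os is antisense to Evx1, and without strand its reads cannot be assigned with certainty. Srsf2, Gm14870 and Snord118 kept their call without any 1 library. For Gm14870 and Snord118 this check could hardly fail, because all their spread lies between the libraries above 0, so it says nothing about how firm these calls are. Without replicates 1 and 2 of iPSC alone the limma adjusted p was 0.205 and 0.187 for Fgf5, 0.139 and 0.129 for Pcsk2 and 0.418 and 0.163 for Evx1os, and without replicate 1 it was 0.139 for Spon1 and 0.474 for Nrcam. Without replicates 1 and 2 of the treated cells it was 0.0985 and 0.157 for Fgf5, 0.0757 and 0.164 for Pcsk2, 0.0697 and 0.367 for Evx1os and 0.0963 and 0.482 for Nrcam, and without replicate 2 it was 0.157 for Spon1. The count was 3 and 5 without replicates 1 and 2 of iPSC alone and 3 without replicate 2 of the treated cells. It was 3 with a pseudocount of 0.1 or a fit of only these 4 libraries, 79 without the filter and 132 with library quality weights.

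In TSC cultured alone, 1625 genes differed with BMP4. The 31 trophoblast stem cell genes went both ways, with 7 higher and 4 lower over all genes. Adjusted over the list alone, 8 were higher and 9 lower (median 0.72, limma camera adjusted p = 0.526). The untreated replicates differed more than 2-fold in 2083 genes and the treated in 1262. Untreated TSC alone also correlated less with the other TSC groups (0.900 to 0.934) than these with each other (0.968 to 0.971). An effect of BMP4 therefore cannot be told from a difference of the untreated libraries. The treated libraries stood apart from each other, with scores of 18.5 and -15.2 on the second principal component, and replicate 1 correlated more with replicate 1 of the assembled TSC part (0.9693) than with its own replicate (0.9561). Eomes stood at 14.0 ± 0.425 FPKM with BMP4 against 0.152 ± 0.0952 (3.71 ± 0.35, limma adjusted p = 7.95e-05, n = 2 per group). The nuclear receptor Nr0b1 (5.89 ± 0.69), the dual oxidase maturation factor Duoxa2 (5.63 ± 0.36), the inositol phosphatase Inpp1 (5.49 ± 0.32) and the imprinted Mest (4.93 ± 0.65) rose. Id2 (2.72 ± 0.42, limma adjusted p = 0.00178) and the BMP pseudoreceptor Bambi (2.94 ± 0.42, limma adjusted p = 0.00134) rose, while Id1 was at 52.2 ± 13.5 with BMP4 and 56.2 ± 69.3 without and did not pass (0.83 ± 0.88; 2.68 with a limma adjusted p of 0.0215 without replicate 2 of TSC alone). Plac1 fell to 15.1 ± 1.27 FPKM (-4.86 ± 0.78, limma adjusted p = 0.00233), the epithelial factor Elf3 to 24.9 ± 4.48 (-3.10 ± 0.51) and Dlx3 to 10.3 ± 3.34 (-2.94 ± 0.30).

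Of the 18 FGF-ERK targets, 9 rose and 1 fell (12 and 1 adjusted over the list alone), with Etv4 at 3.90 ± 0.37, Dusp6 at 3.67 ± 0.43 and Etv5 at 3.58 ± 0.37 (median 1.80, limma camera adjusted p = 4.8e-07; adjusted p = 0.489 with an estimated correlation). Of the 22 epithelial genes, 6 fell and 0 rose (11 and 0 adjusted over the list alone, and 0 higher at an unadjusted limma p under 0.05; median -1.21, limma camera adjusted p = 7.58e-07; adjusted p = 0.499 with an estimated correlation). Of the 16 genes of differentiated trophoblast, 5 fell and 0 rose (6 and 1 adjusted over the list alone; median -1.59, limma camera adjusted p = 0.000902; adjusted p = 0.499 with an estimated correlation). Of the 18 BMP targets, 3 rose and 1 fell (3 and 2 adjusted over the list alone), a list that did not pass (median 0.16, limma camera adjusted p = 0.788). Of the 1625 genes, 856 were higher and 769 lower. The count was 569 without replicate 1 of the treated cells, 428 with library quality weights and 3 in a fit of only these 4 libraries, where each gene named here missed the threshold. Rescaling without predicted names gave 712 higher and 1120 lower and moved the median of all genes from 0.02 to -0.12. With a pseudocount of 0.1 the changes were 5.87 for Eomes, 4.64 for Bambi, 6.32 for Etv4, 5.99 for Dusp6 and 5.81 for Etv5, and the median of the FGF-ERK targets 3.14.

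In the assembled iPSC part, BMP4 changed a single gene past the threshold, and the libraries of the treated group differed widely. Bmp4 RNA was at 90.49 and 20.46 FPKM in the treated libraries against 1.47 ± 0.120 (4.17 ± 0.82, limma adjusted p = 0.240, n = 2 per group; 5.21 and limma adjusted p = 0.0403 without replicate 2 of the treated part). Eomes was at 17.3 ± 1.14 against 3.93 ± 0.372 (1.90 ± 0.35, limma adjusted p = 0.240; 1.83 and limma adjusted p = 0.0405 without the pair of libraries that held genes of the other lineage), Gata3 at 9.24 ± 4.56 against 0.820 ± 0.102 and Fgf5 at 0.593 ± 0.000484 against 9.04 ± 6.35. T was at 326.1 and 94.77 FPKM in the treated libraries and Mixl1 at 214.1 and 9.404. Replicate 2, the lower of each pair, is the library with trophoblast genes at 42.4% of their level in the TSC part.

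Of the 13 genes of extraembryonic mesoderm and amnion, 0 passed over all genes, with 4 higher and 0 lower adjusted over the list alone and 7 and 0 at an unadjusted limma p under 0.05 (median 0.97, limma camera adjusted p = 8.56e-07; adjusted p = 0.140 with an estimated correlation). Of the 18 BMP targets, 0 passed over all genes, with 5 higher and 0 lower adjusted over the list alone and 7 and 0 at an unadjusted limma p under 0.05 (median 0.68, limma camera adjusted p = 5.84e-07; adjusted p = 0.257 with an estimated correlation). Without replicate 1 of the treated part their median was 0.26 (limma camera adjusted p = 0.0980), and it was 1.08 without replicate 2. The 31 trophoblast stem cell genes had 0 past the threshold over all genes, 7 higher and 0 lower adjusted over the list alone and 10 and 0 at an unadjusted limma p under 0.05 (median 1.08, limma camera adjusted p = 1.89e-10; adjusted p = 0.257 with an estimated correlation). Their median was 1.81 and 0.36 without replicates 1 and 2 of the treated part. The single gene that passed, with 1049 at an unadjusted limma p under 0.05, was the predicted gene Gm24151, named by the part of the rule that takes the smallest p. It was at 311.6 and 73.17 FPKM in the treated libraries and 0 in the other 14. The count was 4 without replicate 2 of the untreated part, 44 and 40 without replicates 1 and 2 of the treated part, and 28 without the pair of libraries that held genes of the other lineage. It was 2 with a pseudocount of 0.1, 11 without the filter and 3 (2 higher, 1 lower) after quantile normalization. With predicted names left out and totals rescaled it was 0 in limma, with 1038 at an unadjusted p under 0.05 and the median of all genes moved from 0.05 to 0.16. With a pseudocount of 0.1 the medians were 1.89 for the trophoblast and 1.08 for the BMP genes.

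In the assembled TSC part, BMP4 changed 67 genes. Il5ra, the interleukin 5 receptor, stood at 27.9 ± 2.85 FPKM with BMP4 against 0.590 ± 0.766 (4.27 ± 0.35, limma adjusted p = 8.09e-05, n = 2 per group). Ubd, a ubiquitin-like modifier, stood at 25.5 ± 9.33 against 1.35 ± 0.0157 (3.45 ± 0.27, limma adjusted p = 6.67e-05), Inpp1 at 88.7 ± 19.8 against 10.6 ± 1.10 (2.93 ± 0.32) and the lysophosphatidic acid receptor Lpar6 at 17.3 ± 1.96 against 2.21 ± 0.557 (2.52 ± 0.27). Eomes was at 31.5 ± 3.24 against 20.8 ± 13.6, Id2 at 1042 ± 259 against 1255 ± 247 and Elf5 at 210.2 ± 18.95 against 137 ± 29.9, and none of them passed (limma adjusted p = 0.611, 0.950 and 0.971).

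Of the 22 epithelial genes, 0 passed over all genes, and 14 were lower and 0 higher adjusted over the list alone, as at an unadjusted limma p under 0.05 (median -1.28, limma camera adjusted p = 9.29e-14; adjusted p = 0.336 with an estimated correlation). Their median was -0.71 and -2.001 without replicates 1 and 2 of the treated part. Of the 18 FGF-ERK targets, 0 passed over all genes, with 7 higher and 0 lower adjusted over the list alone and 8 and 1 at an unadjusted limma p under 0.05 (median 0.86, limma camera adjusted p = 0.000141; adjusted p = 0.545 with an estimated correlation). Their median was 0.42 without replicate 1 of the untreated part, and their call was lost without replicate 1 of the treated part (0.77, limma camera adjusted p = 0.0917). The 18 BMP targets had 0 past the threshold over all genes, 1 higher and 1 lower adjusted over the list alone and 2 and 2 at an unadjusted limma p under 0.05, and did not pass (median 0.03, limma camera adjusted p = 0.881). Of the 67 genes, 50 were higher and 17 lower. The count was 18 without replicate 1 and 18 without replicate 2 of the untreated part, 9 and 128 without replicates 1 and 2 of the treated part, and 27 without the pair of libraries that held genes of the other lineage. It was 28 with a pseudocount of 0.1, where Inpp1 lost its call (limma adjusted p = 0.0747). A fit of only these 4 libraries gave 0 in limma, with 1151 at an unadjusted p under 0.05. Rescaling without predicted names moved the median of all genes from -0.03 to 0.08.

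Under BMP4, the assembled iPSC part differed from iPSC alone in Pfkl, in Eomes and in cell cycle genes, and replicate 2 of that part held trophoblast genes at 42.4% of their level in the TSC part. Pfkl stood at 32.1 ± 13.4 FPKM against 182 ± 1.89 (-2.53 ± 0.44, limma adjusted p = 0.0180, n = 2 per group), Eomes at 17.3 ± 1.14 against 2.95 ± 0.136 (2.22 ± 0.35, limma adjusted p = 0.0180) and Srsf2 at 3.52 ± 2.42 against 59.8 ± 7.71 (-3.85 ± 0.41, limma adjusted p = 0.00178). Without replicates 1 and 2 of treated iPSC alone, the limma adjusted p was 0.138 and 0.109 for Pfkl and 0.138 and 0.105 for Eomes, and without replicate 1 of the treated assembled part it was 0.0572 for Eomes. Without the pair of libraries that held genes of the other lineage it was 0.0523 for Pfkl. Srsf2 and Sco2 are the only 2 of 35 changed genes named by the rule that kept their call without any 1 of the 4 libraries. Of 29 cell cycle genes, 10 fell and 0 rose (13 and 0 adjusted over the list alone, and 0 higher at an unadjusted limma p under 0.05; median -0.54, limma camera adjusted p = 0.000718; adjusted p = 0.619 with an estimated correlation). Their median was -0.87 without replicate 2 of the treated assembled part and -0.27 after quantile normalization. In all, 767 genes passed, 118 higher and 649 lower, a split that followed the scaling: 244 and 180 after quantile normalization, 217 and 97 after upper quartile rescaling and 110 and 297 after rescaling without predicted names. The median of all genes, -0.18 as deposited, was -0.02 and 0.06 after the first and second of these. The count was 9 and 5 without replicates 1 and 2 of treated iPSC alone, 47 without replicate 1 of the treated assembled part and 2 in a fit of only these 4 libraries, where Pfkl, Eomes and Srsf2 missed the threshold.

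TSC alone and the assembled TSC part differed in few genes under BMP4. Aldh3b2, an aldehyde dehydrogenase, stood at 0.149 ± 0.154 FPKM in the assembled part against 6.45 ± 0.473 (-2.70 ± 0.27, limma adjusted p = 0.00166, n = 2 per group; -4.87 with a pseudocount of 0.1). The retinoic acid binding protein Crabp1 stood at 28.7 ± 2.61 against 3.76 ± 0.653 (2.65 ± 0.33, limma adjusted p = 0.00762) and the exchange factor Arhgef16 at 1.56 ± 0.432 against 14.3 ± 4.38 (-2.56 ± 0.32, limma adjusted p = 0.00762). Without replicate 2 of treated TSC alone the limma adjusted p of both was 0.0996, and without replicate 1 of the treated assembled part it was 0.0756. Eomes (1.11 ± 0.35, limma adjusted p = 0.178), Elf5 (0.57, limma adjusted p = 0.883) and Id2 (-0.16, limma adjusted p = 0.919) did not pass. Of the 22 epithelial genes, 0 passed over all genes, with 9 lower and 0 higher adjusted over the list alone and 10 and 0 at an unadjusted limma p under 0.05 (median -1.21, limma camera adjusted p = 1.11e-05; adjusted p = 0.664 with an estimated correlation). Their median was -0.29 without replicate 1 of the treated assembled part. In all, 40 genes passed, 21 higher and 19 lower (35 and 18 after upper quartile rescaling). The count was 179 and 4 without replicates 1 and 2 of treated TSC alone and 9 without replicate 1 of the treated assembled part. It was 7 with a pseudocount of 0.1, 8 with library quality weights and 1 in a fit of only these 4 libraries, where the genes named here missed the threshold.

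Whether assembly changed the response to BMP4 was tested directly. For TSC, Etv4 stood at 0.0979 ± 0.0639 FPKM in TSC alone, 15.4 ± 1.05 with BMP4, 20.4 ± 4.67 in the assembled part and 19.9 ± 4.32 in the assembled part with BMP4 (interaction -3.93 ± 0.52, limma adjusted p = 0.00487, n = 2 per group). Ddah1, which degrades asymmetric dimethylarginine, stood at 1.65 ± 0.411, 94.7 ± 22.8, 64.4 ± 12.0 and 75.4 ± 29.5 in the same order (-4.99 ± 0.73, limma adjusted p = 0.00823). The serpin Serpinb9b went the other way, with 58.2, 3.12, 1.32 and 3.54 (4.75 ± 0.50, limma adjusted p = 0.00116), as did the zinc finger gene Zbtb10 (3.23 ± 0.45, limma adjusted p = 0.00639). Eomes differed by -2.98 ± 0.50 (limma adjusted p = 0.0140), a call lost without replicate 1 of treated TSC alone (0.0552), without replicate 1 of the treated assembled part (0.0599) and with library quality weights (0.0540). Across genes, the means of untreated TSC alone correlated at 0.934 with treated TSC alone. They correlated at 0.920 and 0.900 with the assembled TSC part without and with BMP4. The latter groups correlated with each other at 0.968 to 0.971. The interaction therefore cannot tell a changed response to BMP4 from a difference of untreated TSC alone, whose replicates differed more than 2-fold in 2083 genes. In all, 235 genes passed for the interaction, 99 higher and 136 lower in the assembled part. The count was 47 and 144 without replicates 1 and 2 of the assembled part, 47 and 469 without replicates 1 and 2 of treated TSC alone, and 70 and 151 without replicates 1 and 2 of the treated assembled part. It was 155 without the filter, 47 with library quality weights and 12 in a fit of only these 8 libraries, where Zbtb10 and Eomes missed the threshold. Rescaling without predicted names gave 147 higher and 91 lower and moved the median of all genes from -0.06 to 0.22. The interaction with a pseudocount of 0.1 was -6.36 for Etv4 and -5.10 for Eomes.

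For iPSC, 3 genes differed in their response, 2 higher and 1 lower in the assembled part, with 536 at an unadjusted limma p under 0.05. They are the snoRNA Snord118 (6.88) and the predicted genes Gm24151 (7.25) and Gm14870 (-5.65), each listed at 0 in at least 14 of the 16 libraries. The part of the rule that takes the smallest p named them. Srsf2 differed by -3.48 ± 0.58 (limma adjusted p = 0.121), and by -4.06 with a limma adjusted p of 0.0178 without replicate 2 of the treated assembled part. The count was 12 and 8 without replicates 1 and 2 of the treated assembled part and 8 without the pair of libraries that held genes of the other lineage. It was 5 with a pseudocount of 0.1, 13 without the filter and 6 with library quality weights. With predicted names left out and totals rescaled it was 0 in limma, with 518 at an unadjusted p under 0.05 and the median of all genes moved from 0.01 to 0.22.

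Averaged over the 4 contexts, BMP4 raised Eomes by 1.66 ± 0.18 (limma adjusted p = 0.000637, n = 2 in each of 8 groups). Its FPKM with and without BMP4 was 2.95 and 2.22 in iPSC alone, 14.0 and 0.152 in TSC alone, 17.3 and 3.93 in the assembled iPSC part and 31.5 and 20.8 in the assembled TSC part. Dusp6 rose by 1.73 ± 0.22 (131, 13.8, 76.0 and 19.035 with BMP4 against 59.9, 0.125, 44.1 and 6.33 in the same order), and Id2 rose on average by 1.34 ± 0.21 (limma adjusted p = 0.00752). Id2 was at 183, 1196 and 278 FPKM with BMP4 against 43.3, 190.1 and 156 in the first 3 contexts, but at 1042 against 1255 in the assembled TSC part. Bmp4 itself rose by 2.40 ± 0.41 (limma adjusted p = 0.0138; 0.0515 without the filter). The glucose transporter Slc2a1 fell, at 149, 234, 120.2 and 200.1 FPKM with BMP4 against 204, 776, 221 and 389.9 (-1.01 ± 0.14, limma adjusted p = 0.00304), and Fgf5 fell by 1.67. Id1 (1.27 ± 0.44, limma adjusted p = 0.177; 1.73 and 0.00852 without replicate 2 of TSC alone) and Id3 (0.14 ± 0.38, limma adjusted p = 0.918) did not pass.

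Of the 18 FGF-ERK targets, 7 rose and 0 fell on average (13 and 1 adjusted over the list alone; median 0.80, limma camera adjusted p = 1.75e-09; adjusted p = 0.214 with an estimated correlation). Of the 18 BMP targets, 4 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.60, limma camera adjusted p = 3.86e-06; adjusted p = 0.374 with an estimated correlation). Of the 13 genes of extraembryonic mesoderm and amnion, 3 rose and 0 fell (6 and 0 adjusted over the list alone, and 0 lower at an unadjusted limma p under 0.05; median 0.64, limma camera adjusted p = 0.000259; adjusted p = 0.282 with an estimated correlation). The 22 epithelial genes had 0 past the threshold over all genes, 5 lower and 0 higher adjusted over the list alone and 10 and 0 at an unadjusted limma p under 0.05 (median -0.51, limma camera adjusted p = 3.4e-09; adjusted p = 0.296 with an estimated correlation). These averages hide differences between contexts. In iPSC alone, TSC alone, the assembled iPSC part and the assembled TSC part, the epithelial medians were 0.14, -1.21, 0.21 and -1.28. In the same order they were 0.22, 1.80, 0.23 and 0.86 for the FGF-ERK targets and 0.95, 0.16, 0.68 and 0.03 for the BMP targets. Those of the extraembryonic mesoderm genes were 1.54, 0.33, 0.97 and -0.65. In all, 188 genes passed, 148 higher and 40 lower (149 and 81 after quantile normalization, 129 and 60 after upper quartile rescaling), and 75 of them changed at least 2-fold. The count was 60 and 82 without replicates 1 and 2 of iPSC alone, 88 and 96 without those of the assembled iPSC part, and 124 and 77 without those of treated iPSC alone. It was 109 without replicate 2 of the assembled TSC part, 120 without replicate 2 of treated TSC alone and 324 without replicate 2 of the treated assembled iPSC part. Medians with a pseudocount of 0.1 were 1.22 for the FGF-ERK targets, 1.02 for the BMP targets and 1.005 for the extraembryonic mesoderm genes.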

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

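The tests of partner genes, dilution, exposure to BMP4, a library batch, splits of whole groups and a length correction of ribosomal genes were chosen only after the result was seen, and those of GC content, detection, partner RNA across genes and splits for the average effect of BMP4 before.

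The response to BMP4 differed between the assembled TSC part and TSC alone in 235 genes by the interaction in limma. This test cannot tell a changed response from a difference of the untreated libraries of TSC alone, which stood apart from the other TSC groups. The genes picked by the naming rule and past the threshold with a stronger or less negative response in the assembled part were Plac1 (5.13), Serpinb9b (4.75), Dkkl1 (3.74), Rtn1 (3.37), Zbtb10 (3.23), Mtss1l (3.13), Parm1 (3.05), Slco4a1 (3.05), Vgll1 (3.02) and Atp11a (3.01). Those with the opposite sign were Fuom (-5.39), Ddah1 (-4.99), Ly6a (-4.88), Eras (-4.79), Mrpl23 (-4.47), Tmem98 (-4.32), Foxh1 (-3.99), Psors1c2 (-3.93), Etv4 (-3.93), Cd79b (-3.93), Duoxa2 (-3.13), Id2 (-3.00), Eomes (-2.98), Etv5 (-2.50), Klf5 (-2.23) and Spry1 (-1.73). Ly6a belongs to a family of close paralogs, so its reads cannot be placed with certainty. With a pseudocount of 0.1 the call was lost by Plac1, Dkkl1, Rtn1, Vgll1 and Atp11a (limma adjusted p = 0.110, 0.0664, 0.0531, 0.128 and 0.0978). Of these 26 genes, Serpinb9b, Zbtb10, Slco4a1, Fuom, Ddah1, Tmem98 and Etv4 kept their call without any 1 of the 8 libraries. The call was lost by 15 and 8 genes without replicates 1 and 2 of the assembled part, 14 and 9 without those of the treated assembled part, 10 and 5 without those of TSC alone and 18 and 4 without those of treated TSC alone. The count of 235 was 47 and 144, 70 and 151, and 47 and 469 without replicates 1 and 2 of the first, second and last of these groups.

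As lists, the FGF-ERK targets (median of the interaction -1.06), ribosomal protein genes (-0.83) and cholesterol synthesis genes (-0.89) had a lower response to BMP4 in the assembled TSC part and the genes of differentiated trophoblast a higher one (0.93). Their limma camera adjusted p was 0.00657, 2.07e-09, 0.00402 and 0.0285, and for each of the lists the adjusted p was 0.970 with an estimated correlation. Over all genes 3 FGF-ERK targets were lower and 0 higher (6 and 1 adjusted over the list alone), 1 gene of differentiated trophoblast was higher and 0 lower (3 and 1 adjusted over the list alone). None of the ribosomal and cholesterol genes passed over all genes, 1 and 0 were lower adjusted over the list alone, and 22 and 7 were lower and 0 and 1 higher at an unadjusted limma p under 0.05. The FGF-ERK call was lost without replicate 2 of TSC alone (-0.91, limma camera adjusted p = 0.0926), of the assembled part (-0.44, 0.119), of treated TSC alone (-0.79, 0.0589) and of the treated assembled part (-0.90, 0.155). The cholesterol call was lost without replicate 1 of TSC alone (-0.29) and replicate 2 of treated TSC alone (-0.60), and its median was -1.49 without replicate 2 of TSC alone. The ribosomal median was -0.48 without replicate 1 of treated TSC alone and -0.55 after a correction for GC content and transcript length, since changes in this comparison followed length (Spearman 0.241). The call of differentiated trophoblast was lost without replicates 1 and 2 of TSC alone (1.06 and 0.81), replicate 2 of the assembled part (0.56), replicate 1 of treated TSC alone (0.69) and replicate 2 of the treated assembled part (0.63).

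For iPSC, the interaction in limma gave 3 genes, Gm14870 (-5.65), Snord118 (6.88) and Gm24151 (7.25). As lists, trophoblast stem cell genes (median 0.71), neural ectoderm genes (0.77) and p53 and apoptosis genes (0.48) had a higher response in the assembled part, and Wnt targets (-0.32), genes of the state like the early cleavage embryo (-2.15) and ribosomal protein genes (-0.29) a lower one. The limma camera adjusted p was 0.0452, 0.0109, 0.000787, 0.0262, 2.59e-05 and 7.89e-05, against an adjusted p of 0.812, 0.316, 0.812, 0.812, 0.493 and 0.812 with an estimated correlation. Over all genes 0 members of these lists passed, and adjusted over the list alone only 2 neural ectoderm genes did, both higher. At an unadjusted limma p under 0.05, 3, 2 and 1 members of the first lists were higher and 4, 2 and 0 of the others lower, in the same order, with 0 the other way. The trophoblast call was lost without replicates 1 and 2 of iPSC alone (0.61 and 0.67), replicate 1 of the assembled part (0.65), replicate 1 of treated iPSC alone (0.23) and replicate 2 of the treated assembled part (-0.01), and the median was 1.62 without replicate 1 of the last. The neural call was lost without replicate 2 of iPSC alone (0.45), replicate 1 of the assembled part (0.74) and replicate 2 of treated iPSC alone (0.32). The Wnt call was lost without replicate 2 of iPSC alone (0.11), of treated iPSC alone (-0.20) and of the treated assembled part (0.16), and the median was -0.54, -0.51 and -0.77 without replicate 1 of the same groups and -0.18 without replicate 2 of the assembled part. The cleavage embryo list lost its call without replicate 1 of the assembled part (-0.73) and stood at -3.58 without its replicate 2 and at -1.25 without replicate 1 of treated iPSC alone. The ribosomal median was -0.12 without replicate 1 of the treated assembled part and 0.02 after quantile normalization.

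In replicate 2 of the assembled iPSC part with BMP4, 33 trophoblast genes stood at a median of 42.4% of their level in the TSC part (quartiles 30.5 to 57.7). In replicate 1 they stood at 7.49%. The 60 iPSC genes stood at 79.8% in replicate 2 (quartiles 56.4 to 102) and at 80.3% in replicate 1 (54.8 to 120). These medians go against a trophoblast share as large as 42.4%. The quartiles of replicate 2, however, take in 0.576, the level that such a share would leave of an undiluted library. The reference mean of the iPSC genes includes replicate 2 itself, so the level left would lie somewhat above 0.576 here. It also takes treated and untreated libraries together. In replicate 2 of the assembled TSC part, the iPSC genes stood at 14.2% (quartiles 8.03 to 22.0) against 0.648%, so both libraries are consistent with some RNA of the partner part, of a share left open. Of the 3 gene choices tried, each after the outcome of the last was seen, the others gave 57.7% and 13.7% with 1 and 20 genes and 57.9% and 15.9% with 4 and 37. Of 31 genes low in TSC and higher in both treated libraries of iPSC alone than in the untreated ones by at least 1 log2 unit, of which 1 passed in limma, the 28 at 5 FPKM or more in replicate 1 of the treated assembled part stood in its replicate 2 at a median of 0.157 of that level (quartiles 0.0956 to 0.289), and all 31, added later since that minimum can lower the ratio, at 0.164 (0.111 to 0.343), where dilution by 42.4% would leave 0.576, which argues against dilution as the whole cause of its weak response. Between the untreated part (0) and replicate 1 (1), replicate 2 lay at -0.42 over these 31 genes and at 0.575 over 18 lower by the same rule, of which 2 passed; values divided by the share left for iPSC RNA, added after this was seen, gave 0.26 and -0.21, 0.27 and -0.21, 0.01 and 0.09, or -0.25 and 0.38, so a structure not reached by BMP4, a wrong treatment label and a biological difference between structures stay open.

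Of 18 FGF-ERK targets, 9 were lower in untreated TSC alone than in the assembled TSC part and 1 higher (median change 1.44, limma camera adjusted p = 8.57e-07; adjusted p = 0.336 with an estimated correlation). GC content and transcript length are argued against, since 10 of the 10 called members stayed past the threshold after a correction for them and the median was 1.47. A general loss of detection is argued against too, since the median lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 0.99 and whose central range was -0.50 to 0.39. The median also rose by 1.80 with BMP4 in TSC alone, so a difference between assembled libraries and those of cells cultured alone does not cover it, but a difference of the untreated TSC libraries alone stays open. A lower response to FGF4 in these colonies is a candidate explanation that was not tested.

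Libraries of assembled cells stood apart from those of cells cultured alone, with 46 genes higher and 249 lower in all 8 assembled libraries than in the other 8; of the 35 splits of whole groups into 4 and 4, 2 gave at least these 295, the real one and that by cell type with 1251, a structure of the samples, so chance cannot be excluded by this count although the next highest gave 61. GC content and length are argued against as the whole cause, since 286 genes separated them after the correction, but the balance moved to 125 higher and 161 lower. RNA of the partner part would move each part towards the other. The change with assembly in iPSC and that in TSC under BMP4 instead correlated positively across genes (Pearson 0.360, Spearman 0.415). This argues against such RNA as the whole cause, though genes are not independent replicates. The assembled libraries behind that value held little of the partner genes, with medians of 4.60% and 6.42% in the iPSC part and 1.18% and 3.60% in the TSC part. The libraries that held 42.4% and 14.2% enter the comparison of iPSC under BMP4 with untreated TSC, where Pearson's r was 0.168. A library batch that follows assembly cannot be told apart from assembly, because the labels give no batch and the position of TSC alone with BMP4 between TSC alone (0) and the assembled TSC part (1), over 158 genes higher and 791 lower in all libraries of the assembled iPSC part than in those of iPSC alone, was 0.219 and -0.624. Assembly itself, as a biological difference, stays open.

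For the average effect of BMP4, the real split gave 188 genes and the highest of the other splits 171. Of 100 splits, 1, the real one, gave as many, so chance is argued against for that count. It is not excluded, since 1 of 100 is the smallest share these splits can give and others gave 171, 166 and 122 genes.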

How the results depend on the processing

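The fits with predicted names left out and totals rescaled, and without replicate 2 of the treated assembled iPSC part and replicate 2 of the assembled TSC part, were chosen only after the result was seen. Of 196 alternative counts of changed genes, 115 stayed within 1.5 times the count reported and 81 moved. For named genes past the threshold, 1842 of 2852 calls were kept on leaving out 1 library, 482 of 573 with library quality weights, 424 of 573 without the filter and 224 of 536 in a fit of only the groups compared. They were kept in 491 of 573 with a pseudocount of 0.1, 525 of 573 after quantile normalization, 533 of 573 after upper quartile rescaling and 550 of 567 after rescaling without predicted names, and 0 reversed in limma. For lists, limma camera kept 451 of 536 calls on leaving out 1 library, 98 of 103 with library quality weights, 92 of 103 with a pseudocount of 0.1 and 86 of 103 after quantile normalization. With 1 library left in a group, the fit assumes that it varies like the others. A fit of only the groups compared has fewer libraries behind each gene's spread. It also no longer shares that spread with the other groups, whose replicates differed unequally. Replicates differed more than 2-fold in 2083 genes in TSC alone and in 454 in iPSC alone. The fit of all groups can therefore make p-values of comparisons with TSC alone too small. Which of these lowered the counts was not tested. Without predicted names, the genes counted in the iPSC interaction and the BMP4 effect of the assembled iPSC part are themselves left out. The cause of the other moves was not tested. Depth is unknown, so how far it limits calls of low genes cannot be stated.

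With a pseudocount of 0.1 the count was 3 for BMP4 in iPSC alone, 2 in the assembled iPSC part, 28 in the assembled TSC part, 7 for the TSC parts under BMP4 and 5 for the iPSC interaction. Without the filter it was 79 for BMP4 in iPSC alone, 11 in the assembled iPSC part, 13 for the iPSC interaction and 155 for the TSC interaction. Quantile normalization gave 3 for BMP4 in the assembled iPSC part and 424 for assembled against lone iPSC under BMP4, and upper quartile rescaling gave 314 for the latter. Library quality weights gave 3985 for assembled against lone iPSC and 1510 for TSC, 132 for BMP4 in iPSC alone and 428 in TSC alone, 8 for the TSC parts under BMP4, and 6 and 47 for the iPSC and TSC interactions. A fit of only the groups compared gave 3 for assembled against lone TSC, 3 for BMP4 in iPSC alone, 3 in TSC alone and 0 in the assembled TSC part (limma, with 1151 at an unadjusted p under 0.05). It gave 2 and 1 for assembled against lone iPSC and TSC under BMP4, and 12 for the TSC interaction. A threshold of 2-fold gave 75 for the average effect of BMP4.

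A replicate block, with replicate numbers as a term, gave 17 for the TSC parts under BMP4 and 134 for the TSC interaction. The deviations of replicates with the same number correlated at -0.185 to 0.1185 across genes. These values show no common pairing. With 2 libraries per group they cannot exclude that libraries with the same number share a structure or preparation. With predicted names left out and totals rescaled, limma gave 0 for BMP4 in the assembled iPSC part (1038 at an unadjusted p under 0.05), 0 for the iPSC interaction (518) and 407 for assembled against lone iPSC under BMP4. Without the pair of libraries that held genes of the other lineage, the count was 1740 for the assembled parts against each other, 1398 for assembled against lone TSC, 676 for assembled against lone iPSC under BMP4, 28 and 27 for BMP4 in the assembled iPSC and TSC parts, and 8 for the iPSC interaction.

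Leaving out 1 library at a time gave 3087 to 4292 genes for TSC against iPSC alone, 902 to 1473 for the assembled parts, 6 to 739 for assembled against lone iPSC and 1038 to 2083 for TSC. It gave 3 to 6 for BMP4 in iPSC alone, 569 to 1641 in TSC alone, 1 to 44 in the assembled iPSC part and 9 to 128 in the assembled TSC part. The range was 5 to 857 and 4 to 179 for assembled against lone iPSC and TSC under BMP4, 3 to 12 and 47 to 469 for the iPSC and TSC interactions and 60 to 324 for the average effect.

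Among lists, 6 of the alternatives reversed the direction of the limma camera test. Ribosomal protein genes of assembled against lone iPSC under BMP4 had a median of 0.16, and -0.0591 after quantile normalization, and those of TSC had 0.13, and -0.14 and 0.52 without replicates 2 and 1 of treated TSC alone. Cleavage embryo genes under BMP4 in iPSC alone had a median of 0.75, and -0.17 and 1.66 without replicates 1 and 2 of the treated cells. Pluripotency genes under BMP4 in the assembled TSC part had a median of -0.16 and a mean of -0.11 with an upward test direction that did not pass, and a median of -0.45 with a downward one without replicate 1 of the untreated part, against 0.43 without its replicate 2, also when the other doubted library was left out with it. Trophoblast genes in the iPSC interaction had a median of 0.71, 1.62 without replicate 1 of the treated assembled part, and -0.0104 without its replicate 2 as well as without the pair of libraries that held genes of the other lineage.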

Other observations

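The test of interferon genes was chosen only after the result was seen. Genes of the pluripotency list went both ways between the assembled parts. In the TSC part, Esrrb stood at 13.4 ± 5.87 FPKM against 0.243 ± 0.0607 in the iPSC part (3.47 ± 0.68, limma adjusted p = 0.00448, n = 2 per group) and Tfcp2l1 at 19.4 ± 2.37 against 0.425 ± 0.0352 (3.83 ± 0.67, limma adjusted p = 0.00255), while Nanog and Pou5f1 were lower and Sox2 did not pass (1.20, limma adjusted p = 0.207). Of 28 pluripotency genes, 7 were higher and 7 lower in the TSC part over all genes and adjusted over the list alone (median -0.03, limma camera adjusted p = 0.566). In TSC alone against iPSC alone, 15 were lower and 4 higher, the same counts adjusted over the list alone (median -1.48, limma camera adjusted p = 0.00887; adjusted p = 0.529 with an estimated correlation). The change of Esrrb with a pseudocount of 0.1 was 5.23.

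Imprinted genes parted between the cell types without a common direction. Of 18 measured, 8 were higher and 7 lower in TSC alone than in iPSC alone, the same counts adjusted over the list alone (median 0.69, limma camera adjusted p = 0.285), with Cdkn1c at 326 ± 217 against 1.25 ± 0.416 FPKM (7.02 ± 0.69, limma adjusted p = 2.1e-05, n = 2 per group). In the assembled TSC part, Peg10, a gene the placenta needs, was at 14.7 ± 5.77 against 158 ± 8.08 in TSC alone (-3.38 ± 0.54, limma adjusted p = 0.00167; 0.0725 in a fit of only these 4 libraries). Of 18 cholesterol synthesis genes, 7 rose and 1 fell in the assembled TSC part against TSC alone (9 and 1 adjusted over the list alone; median 0.96, limma camera adjusted p = 8.49e-05; adjusted p = 0.698 with an estimated correlation). Nsdhl rose by 1.84 ± 0.28 and Cyp51 by 1.90 ± 0.37, and in a fit of only these 4 libraries both missed the threshold (limma adjusted p = 0.0827 and 0.108). The median of that list was 0.37 and 1.72 without replicates 1 and 2 of TSC alone. Epithelial genes were higher in TSC alone than in iPSC alone, with 12 of 22 higher and 2 lower (13 and 2 adjusted over the list alone; median 1.42, limma camera adjusted p = 0.000178; adjusted p = 0.492 with an estimated correlation), among them the claudin Cldn3 (4.93 ± 0.60).

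A list of interferon-stimulated genes was written after the values were seen. Of its 37 tested members, 34 had a positive change with BMP4 in iPSC alone (median 1.21, limma camera p = 0.0681 with an estimated correlation). There, 0 passed over all genes in limma, with 15 higher and 0 lower adjusted over the list alone and 17 and 0 at an unadjusted p under 0.05. In TSC alone, 3 were higher and 8 lower over all genes (4 and 8 adjusted over the list alone). The median was -0.30 in TSC alone, 0.50 in the assembled iPSC part and 0.43 in the assembled TSC part. For the average effect of BMP4 the limma camera p with an estimated correlation was 0.367, so an interferon-type response in the treated libraries is neither shown nor ruled out.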
